A study of Homo sapiens with 9 samples.

How the data were processed

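Blood preparations of 6 patients with Sézary syndrome and 3 healthy donors were profiled on Illumina expression bead arrays, 1 array per sample, from 250 ng of RNA per the labels' protocols. The labels placed 3 patients in a group with a dominant clone and high burden (SS clonal) and 3 in a group without one and with medium to low burden (SS non-clonal). The source label of the healthy donors names mononuclear blood cells while the design text names CD4 T cells, and the chip name in the labels and the number of probes in the files do not match, so neither point is settled here. Replicate numbers follow the order of the samples and do not pair them. Each sample is a separate donor per the labels.

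The deposited files of single arrays hold 1 linear intensity per probe, with no background subtraction or normalization between arrays visible in the values. BeadStudio is named per the submitters' processing notes. They hold no detection p-value and no slide or scan date, so batches could not be tested. Raw intensities ranged from 41.2 to 55531, with a median per array from 70.3 to 88.7. The table of the whole series holds the authors' processed intensity values for 27167 probes on a linear scale, with medians of 134.373 to 134.417 per column. For 99.85% to 99.97% of its probes it equals, within 0.1%, the quantile-normalized values obtained by taking the median over arrays at each rank, and all 9 columns matched their own array. Its scale was found to be linear in this way, and the rule by which the authors kept probes and the version of the software are not given in the sources used here.

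The test planned for files with detection p-values was replaced by the alternative fixed for files without them. Intensities were background-corrected by normexp with an offset of 50, quantile-normalized and taken to log2 with limma 3.58.1 in R 4.3.3. A probe was above background on an array when its raw log2 intensity exceeded the mode of that array by 2.326 SDs of the values below the mode, a threshold set for these files. The 20353 probes above it on at least 3 arrays were kept. The number of probes above background was 16377 to 17400 in healthy donors, 18015 to 19459 in SS non-clonal and 18615 to 19980 in SS clonal patients. Gene names came from the platform annotation, which listed 18788 probes, 18782 with 1 symbol and 6 with several, and 18767 matched a current gene entry. The 30021 probes of the files without a single symbol there, which include these 6, entered under their own identifier. Of a gene's kept probes the one with the highest mean was used, which concerned 2993 genes with several. Another probe of a called gene was itself called in the opposite direction for 1 gene in the comparison of all patients and 2 in that of SS clonal patients with healthy donors. For the donors' privacy 52 kept probes were left out, those of sex-linked, HLA, T cell receptor and immunoglobulin genes and of genes with common null genotypes. This left 16374 features, 11285 with a symbol and 5089 without.

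A limma model (lmFit and eBayes) with 3 groups was fitted to all 9 arrays, with 6 residual and 2.789 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all features at 0.05. The contrasts were the mean of both patient groups against healthy donors, each patient group against healthy donors, and SS clonal against SS non-clonal. The title genes were also tested by exact permutation. A gene not above background on any array of a group was given a bound against the lowest normalized intensity above background. Quantile normalization gives every array the same distribution, so changes are relative to it, and an offset of 50 shrinks fold changes of dim genes. No pair of arrays held identical values.

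The 29 gene lists, 20 of T cell states and pathways and 9 of other cell types, were fixed before the data were examined, as were the tests, most of the other settings tried and the rule for naming genes. The background threshold was set after the files were seen to hold no detection p-value. Lists were tested by camera with a preset correlation of 0.01 between genes, by camera with an estimated correlation and by fry, adjusted over the lists of a comparison. Genes named were CD164, FCRL3 and DPP4. Next came genes past the test with a log2 fold change of at least 1 and no overlap of single values, the 10 largest rises and 10 largest falls for all patients and 5 and 5 for other comparisons. Where fewer than 5 passed, those with the smallest unadjusted p were named as failed. Of each list described, up to 4 members past the test were named by smallest p, or the 2 with the largest change.

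The procedure was tested on simulated data with 200 changed features of 16374. Changes of 1, 2 and 3 on the log2 scale were recovered for 59.1%, 91.0% and 94.0% of features in all patients against healthy donors. The shares were 54.5%, 77.6% and 95.5% for SS clonal and 56.1%, 92.5% and 92.5% for SS non-clonal patients against healthy donors, and 66.7%, 88.1% and 91.0% between the patient groups. No change was called in the wrong direction, and false calls made up 4.12%, 7.32%, 6.40% and 6.29% of calls in that order. Of 20 lists shifted by 0.5 all 20 were recovered, with 0 of 200 unshifted lists called. The simulated noise was independent between features, so this does not test the calls of lists whose genes are correlated. Alternatives covered the background correction, normalization, probe filter, probe choice, variance model, array weights, the samples in the fit, the authors' values and leaving out each sample. Figures were drawn with matplotlib 3.10.9.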

Results

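Gene expression was measured in preparations from the blood of 6 patients with Sézary syndrome, a leukemic form of cutaneous T cell lymphoma in which malignant CD4 T cells circulate, and of 3 healthy donors. The design text names CD4 T cells, while the source label of the healthy donors names mononuclear blood cells, so a difference in cell composition between patients and healthy donors was not excluded. Per the labels, 3 patients had 1 dominant T cell clone and a high circulating tumor burden (SS clonal) and the other 3 had no such clone and a medium to low burden (SS non-clonal). Each sample was hybridized to 1 Illumina bead array of gene-specific probes. The number of arrays limits the precision of each value. Median raw intensity per array ranged from 70.3 to 88.7, against a highest raw intensity of 55531. The 3 SS clonal arrays had 19399 ± 705 probes above background (SD, n = 3), the SS non-clonal arrays 18957 ± 816 and the healthy donor arrays 16956 ± 525. Expression is given as log2 normalized intensity, and a fold change as a difference on that scale. The first principal component held 34.3% of the variance, with the 3 SS clonal samples between -55.3 and -28.2 and the 3 healthy donors between 21.9 and 37.1. On it SS non-clonal 1, 2 and 3 lay at -3.73, 13.8 and 22.5, the last within the range of the healthy donors. The second component, with 20.0%, placed SS non-clonal 1 at -65.8 and the other 8 samples between -4.20 and 17.0.

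The series title names 3 genes, CD164, a sialomucin of the cell surface, FCRL3, an Fc receptor-like membrane protein, and DPP4, which encodes the peptidase CD26. CD164 was 8.52 ± 0.33 in SS clonal, 8.56 ± 0.23 in SS non-clonal and 7.63 ± 0.26 in healthy donors (SD, n = 3 each), and all 6 patients lay above all 3 healthy donors. The mean of both patient groups was 0.91 above the healthy donors (SE 0.18, adjusted p = 0.039 by limma), a 1.88-fold difference. FCRL3 was 11.60 ± 0.11 in SS clonal, 8.32 ± 1.87 in SS non-clonal and 7.66 ± 0.42 in healthy donors. It rose 15.4-fold in SS clonal patients (log2 fold change 3.94, SE 0.76, adjusted p = 0.022), whereas over all patients the change of 2.30 did not pass (adjusted p = 0.089) and the difference between the patient groups of 3.27 did not pass either (adjusted p = 0.080). DPP4 was 7.26 ± 0.76 in SS clonal, 8.94 ± 0.74 in SS non-clonal and 9.22 ± 0.40 in healthy donors.

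DPP4 fell by 1.96 in SS clonal patients (SE 0.45, adjusted p = 0.037), and the change over all patients of -1.12 did not pass (adjusted p = 0.14). In two-sided exact permutation tests of 6 patients against 3 healthy donors, CD164 gave p = 0.0119, the smallest that the 84 splits allow, FCRL3 p = 0.143 and DPP4 p = 0.155. With Benjamini-Hochberg adjustment over these 3 tests the permutation p became 0.0357 for CD164 and 0.155 for FCRL3 and DPP4. CD164 and FCRL3 were named by the study from these samples, so these values are not independent evidence for them. The CD164 call was held in 1 of 9 fits that left out a single sample: it was lost without SS clonal 1 or 3, any SS non-clonal sample or any healthy donor, with adjusted p from 0.0517 to 0.166, while its log2 fold change stayed between 0.76 and 1.001. Without SS non-clonal 1 FCRL3 passed over all patients at 2.72 (adjusted p = 0.034), and without SS non-clonal 3 it passed at 1.80 (adjusted p = 0.039). Among SS clonal patients the FCRL3 call was lost without SS clonal 3 or any healthy donor (adjusted p from 0.0577 to 0.0832), and the DPP4 call without SS clonal 2 or 3, SS non-clonal 2 or any healthy donor (adjusted p from 0.0519 to 0.114). The DPP4 call was also lost with median scaling and with no filter on dim probes (adjusted p = 0.0554 and 0.0728). With the level of NK and CD8 T cell markers as a covariate DPP4 moved from -1.96 (SE 0.45) to -2.17 (SE 0.49) and its unadjusted p from 0.0020 to 0.0023. Its call ended (adjusted p = 0.0572) because fewer features were called in that fit, where the largest unadjusted p called was 0.0016 instead of 0.0038. The difference in FCRL3 between the patient groups passed without SS non-clonal 3, at 4.29 (adjusted p = 0.0097), and with the marker covariate, at 4.94 (adjusted p = 0.024).

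**Figure D1:**
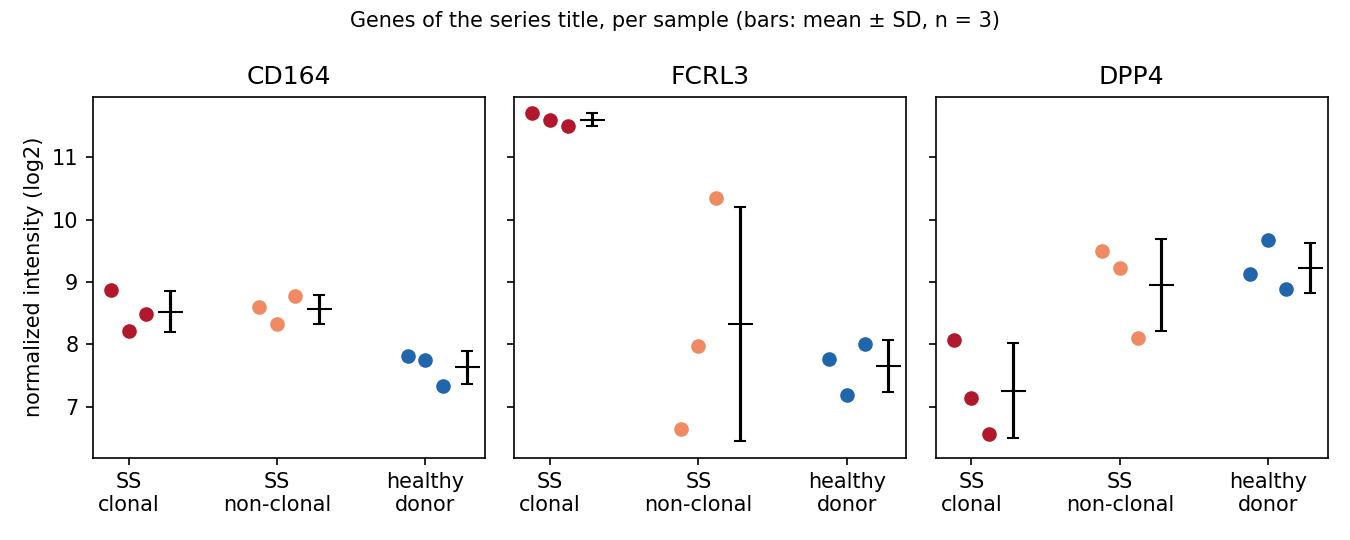
Normalized intensity (log2, vertical axis) of CD164, FCRL3 and DPP4 in each sample (points) of the 3 groups, with the group mean ± SD (bars, n = 3). CD164 was 8.52 and 8.56 on average in the patient groups against 7.63 in healthy donors, and FCRL3 was 11.60 in SS clonal patients against 7.66.

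The title also names an inverse relation of CD164 and CD26. At the level of RNA in these preparations, CD164 and DPP4 had Pearson's r = 0.14 over the 6 patients (exact permutation p = 0.756) and Spearman's rho = 0.20 (exact permutation p = 0.714), the only pair of genes tested in this way. Without the 2 patients farthest from the median of CD164, r was -0.14 (exact permutation p = 0.917). Patients and healthy donors formed separate clusters in CD164, so no value over all 9 samples was computed. Array values average over all cells of a preparation and do not address a relation between cells.

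The comparison of all patients with healthy donors asked which genes differ in blood preparations of Sézary syndrome. The 10 largest rises among genes whose single values did not overlap were those of NHERF1, a PDZ scaffold protein, at 1.90 on the log2 scale (SE 0.37, 3.73-fold), TOX, a nuclear factor of T cell development and exhaustion, at 1.86 (SE 0.26, 3.63-fold), the heat shock gene HSPA1A at 1.81 (SE 0.23, 3.52-fold), TWIST1, a basic helix-loop-helix factor, at 1.79 (SE 0.38), ANXA2P1 at 1.77, the lymphocyte receptor SLAMF6 at 1.72, RAB37 at 1.69, PCMT1 at 1.58, the stress granule protein G3BP1 at 1.56 and METTL13 at 1.55. ANXA2P1 is a pseudogene of ANXA2, and its probe cannot be assigned with certainty to either. HSPA1A likewise has a near-identical copy, HSPA1B, so its value is uncertain. The 10 largest falls among such genes were those of ZSCAN18 (6.68-fold), GPR132, a G protein-coupled receptor (6.46-fold), CDKN1A, the cell cycle inhibitor p21 (5.83-fold), SCML1 (5.79-fold), WNT7A (5.41-fold), VIPR1, a receptor of vasoactive intestinal peptide (5.40-fold), SC5D, an enzyme of cholesterol synthesis (4.89-fold), GSTM3 (4.79-fold), ZNF331 (4.49-fold) and SATB1, a chromatin organizer of T cells (4.36-fold). Adjusted p of these 20 genes ranged from 0.0072 for SC5D to 0.0482 for CDKN1A. Not above background on every patient array were GPR132 and SATB1 (2 of 3 SS clonal arrays), WNT7A (2 of 3 in each patient group) and GSTM3 (1 of 3 SS clonal and 2 of 3 SS non-clonal arrays). Under 20 or 21 other settings per gene these calls were lost in 2 (SC5D, GSTM3) to 14 (CDKN1A), and with the mean of a gene's probes the CDKN1A log2 fold change was -1.71 in place of -2.54. TWIST1 was 10.18 ± 1.08 in SS clonal, 7.49 ± 0.23 in SS non-clonal and 7.05 ± 0.07 in healthy donors, and its change differed between the patient groups (adjusted p = 0.034).

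In total 557 of 16374 features (genes, or probes without a gene name) passed at an adjusted p of 0.05 by limma, 256 higher and 301 lower in patients, of which 76 and 108 changed at least 2-fold. The single values of the groups did not overlap for 12.8% of the features, against 2.38% by chance. The count rested on the healthy donors: it was 0 without healthy donor 1 or 3 (2501 and 2449 at an unadjusted p of 0.05) and 27 without healthy donor 2, it was 261 without SS clonal 3, 245 without SS non-clonal 2 and 332 without SS non-clonal 3, and it was 2572 with array weights and 166 with the 6 patients as 1 group. With median scaling in place of quantile normalization 379 features were higher and 153 lower, and the median of all features shifted by 0.12, so directions are relative to the quantile-normalized distribution.

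**Figure D2:**
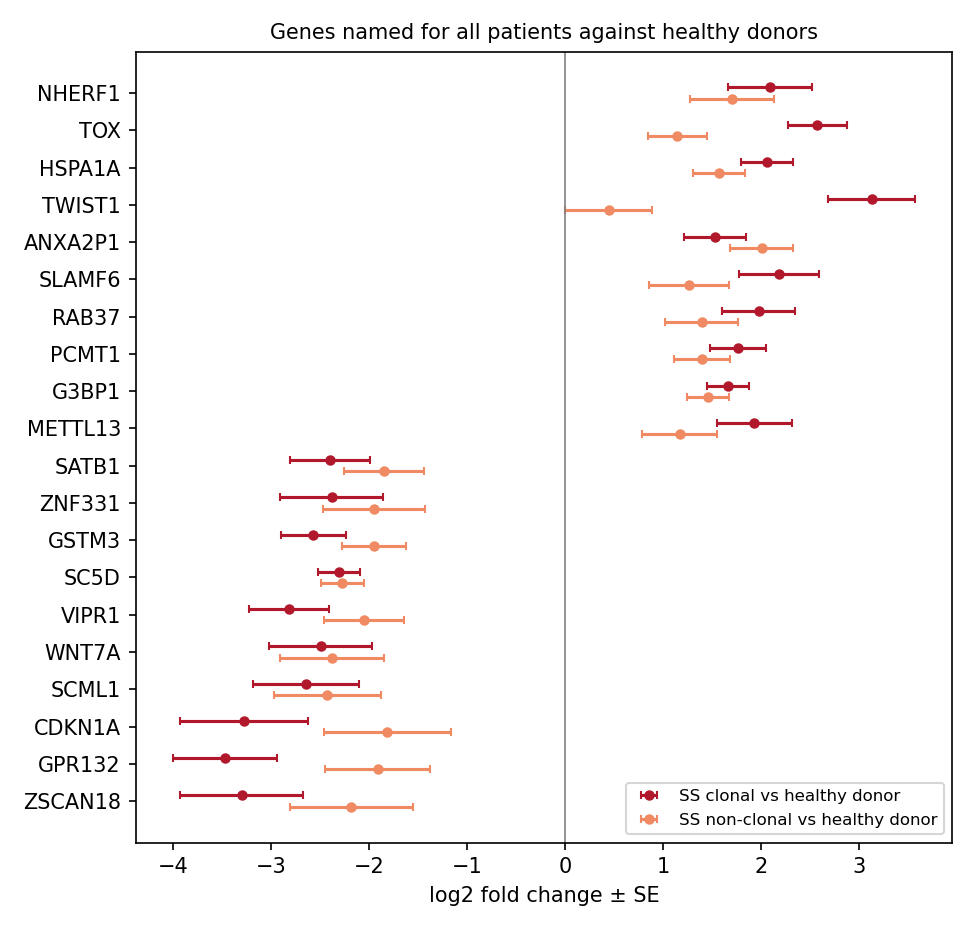
Log2 fold change (horizontal axis, ± SE from limma) of the 20 genes named for all patients against healthy donors, shown for SS clonal and for SS non-clonal patients. TWIST1 changed by 3.13 in SS clonal and 0.45 in SS non-clonal patients, and SC5D by -2.31 and -2.27.

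Among the gene lists fixed before the data were examined, genes that have been described as raised in Sézary cells were higher in patients. Of 23 measured members 20 were higher, 4 rose over all genes tested and 15 rose when adjusted over the list alone. GTSF1, a germ cell-associated zinc finger gene, rose 4.54-fold (adjusted p = 0.018), followed by TOX, CD164 and TWIST1. The median change was 1.11, and the list passed camera (adjusted p = 1.33e-06) and also with an estimated correlation (adjusted p = 0.027). The list includes CD164 and FCRL3, which the study chose on these samples. SS clonal patients carried most of this rise. In SS non-clonal patients the median was 0.30, with 17 of 23 higher, none past the test over all genes, only CD164 and TOX past it over the list alone, and an adjusted p of 0.19 by camera. Of 14 genes described as lowered, 11 were lower, with a median change of -0.65. TGFBR2, a TGF-beta receptor subunit, fell 4.05-fold (adjusted p = 0.025) and SATB1 fell, while TNFSF10, which encodes the death ligand TRAIL, rose 4.57-fold (adjusted p = 0.041), and 5 members fell and 1 rose when adjusted over the list alone. This list passed camera (adjusted p = 0.017) but not with an estimated correlation (adjusted p = 0.76), nor without healthy donor 2 (adjusted p = 0.065), and its median was -0.34 without SS clonal 3.

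Interferon-stimulated genes were higher in patients for 22 of 25 members, with a median change of 0.55. OAS2, an antiviral oligoadenylate synthetase, rose 2.66-fold (adjusted p = 0.038) and IFI35 rose 1.87-fold (adjusted p = 0.038), and 6 members rose when adjusted over the list alone. Proliferation genes were higher for 26 of 27 members, with a median change of 0.52. The replication licensing factor MCM3 rose 2.27-fold (adjusted p = 0.023), and 2 members rose over the list alone. TGF-beta signalling genes were lower for 12 of 15 members, with a median change of -0.37. SMAD7, an inhibitor of TGF-beta signalling, fell 4.54-fold (adjusted p = 0.043) beside TGFBR2, and 4 members fell over the list alone. Ribosomal protein genes were lower for 45 of 62 members, with a median change of -0.13. RPL32 fell 1.68-fold (adjusted p = 0.031) and RPS9 fell 1.53-fold (adjusted p = 0.041), with 5 lower and 1 higher over the list alone. These 4 lists passed camera (adjusted p = 0.00028, 0.00089, 0.016 and 0.012, in that order) and none passed with an estimated correlation (adjusted p = 0.78, 0.79, 0.76 and 0.76). Without SS non-clonal 2 the proliferation median was 0.27 (adjusted p = 0.0053). Without healthy donor 3 the TGF-beta median was -0.18 and did not pass (adjusted p = 0.056), nor did the ribosomal list without healthy donor 2 (adjusted p = 0.084). With median scaling the ribosomal median was -0.37, and no called list changed direction with median scaling or cyclic loess.

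The other T cell lists did not pass camera for all patients. BATF, a transcription factor of the Th17 list, rose 2.42-fold (adjusted p = 0.033), while 4 of the 6 Th17 genes were lower. IKZF2, which encodes Helios, rose 1.67-fold (adjusted p = 0.049) in the regulatory T cell list, where 9 of 12 genes were higher. TOX rose in the list of T follicular helper and checkpoint genes, with 8 of 12 higher, and CD164 in the list of skin homing and adhesion, with 9 of 13 higher. Among cell death regulators TNFSF10 rose and the TRAIL receptor TNFRSF10B fell 1.46-fold (adjusted p = 0.041), with 6 of 16 genes higher. NDUFB3 rose 1.87-fold (adjusted p = 0.042) and NDUFB7 rose 1.41-fold (adjusted p = 0.042) among 27 NADH dehydrogenase subunits, of which 19 were higher. Adjusted over the list alone, BACH2 fell 3.02-fold among naive and central memory genes (8 of 10 lower), MYC rose 2.16-fold among immediate early genes (12 of 18 lower) and FCRL3 rose among 3 Fc receptor-like genes, all higher. No member passed in the other lists. In the Th2 list 4 of 8 genes were higher, with GFI1 at -0.96 and GATA3 at 0.90, and its median of -0.28 and the upward direction of its test differed. In the Th1 list 6 of 12 were higher, with STAT4 at -1.59 and CXCR3 at -1.44. Of the NF-kB targets 12 of 15 were lower, with CD83 at -0.97 and TNFAIP3 at -0.96, and of the T cell receptor signalling genes 14 of 21 were higher, with TXK at -2.06 and CD5 at -1.11. Camera gave adjusted p from 0.17 to 0.83 for these 13 lists and the list of title genes (adjusted p = 0.43).

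None of the 9 lists of other cell types passed camera for all patients. Erythroid genes were higher for 5 of 5 members, with a median change of 1.95 (adjusted p = 0.23), HBB at 2.60 and HBA1, whose value is uncertain as HBA2 is a near-identical copy, at 2.48. Of the CD8 T cell genes 4 of 5 were lower, with GZMK at -1.73 and CCL5 at -1.71 (adjusted p = 0.46), and of the NK cell genes 6 of 10 were higher, with PRF1 at 1.04 and KLRF1 at 0.91 (adjusted p = 0.83). Monocyte genes were lower for 9 of 12 members, with FCER1G at -0.95 and TYROBP at -0.80 (adjusted p = 0.72). In the B cell list CR2 fell 1.43-fold (adjusted p = 0.041) and 5 of 7 genes were higher, so its median of 0.15 and the direction of its test differed (adjusted p = 0.83). MMP9 fell 3.48-fold in the neutrophil list when adjusted over the list alone, with 3 of 5 genes lower. Dendritic cell genes were lower for 4 of 5, with FCER1A at -0.93 and CD1C at -0.28. Platelet genes, with PPBP at 0.09 and TREML1 at -0.08, and eosinophil and basophil genes, with EPX at 0.52 and PRG2 at 0.10, numbered 4 each. Camera gave adjusted p of 0.80 for neutrophil, 0.63 for dendritic cell, 0.83 for platelet and 0.73 for eosinophil and basophil genes.

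SS clonal patients, the group with a dominant clone and a high burden, had their largest rise, among genes whose single values did not overlap, in PLS3, which encodes the actin-bundling protein plastin 3. PLS3 rose 48.0-fold, from 6.57 ± 0.16 to 12.16 ± 1.99 (adjusted p = 0.010). DNM3, a dynamin, rose 18.9-fold (adjusted p = 0.0090), FCRL3 15.4-fold and GTSF1 by 3.58 on the log2 scale (adjusted p = 0.0026). CEMIP, a hyaluronan-binding protein, rose at least 7.84-fold (adjusted p = 0.0091), a bound against the lowest intensity above background because it was not above background on any healthy donor array. PLS3 and DNM3 were above background on 2 of 3 healthy donor arrays, so the size of their rises is uncertain. The largest falls among such genes were those of SMAD7, from 11.17 ± 0.87 to 7.18 ± 0.68 (adjusted p = 0.0091), AUTS2 (12.2-fold, adjusted p = 0.014), the homeodomain-only protein HOPX (11.2-fold, adjusted p = 0.011), GPR132 (11.1-fold, adjusted p = 0.014) and NBL1 (10.9-fold, adjusted p = 0.023). Of these, all but HOPX were above background on 2 of 3 SS clonal arrays, and the HOPX log2 fold change was -1.78 with the mean of its probes in place of -3.49, so the size of all 5 falls is uncertain. These 10 calls were lost in 0 to 4 of 20 to 22 other settings. CD164 rose 1.85-fold (adjusted p = 0.040), a call that was lost without SS clonal 1 or 3 or any healthy donor (adjusted p from 0.079 to 0.14), with no filter and with only the groups compared (adjusted p = 0.063 and 0.051). With the marker covariate CD164 moved from 0.89 (SE 0.21) to 0.96 (SE 0.24) and its unadjusted p from 0.0024 to 0.0036, above the same 0.0016 (adjusted p = 0.068).

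Genes described as raised in Sézary cells had a median change of 1.97 in SS clonal patients, and 14 of 23 rose (15 adjusted over the list alone), among them TOX (5.95-fold, adjusted p = 0.0068), with an adjusted p of 1.07e-09 by camera and an adjusted p of 0.0097 with an estimated correlation. Of the genes described as lowered 4 fell and 1 rose (7 and 2 adjusted over the list alone), including TGFBR2 (8.79-fold lower, adjusted p = 0.0068), SATB1 (5.27-fold lower, adjusted p = 0.017) and the death receptor FAS (1.87-fold lower, adjusted p = 0.017), against TNFSF10 (7.82-fold higher, adjusted p = 0.018). Of the interferon-stimulated genes 4 rose (5 adjusted over the list alone), IFI35, RIGI, OAS2 and SAMD9L, by 2.13-fold to 3.36-fold. In the TGF-beta list TGFBR2, SMAD7 and TGFB1 (2.92-fold) fell. Of the ribosomal protein genes 4 fell (5 adjusted over the list alone), RPL26, RPS9, RPL32 and RPL28, by 1.74-fold to 2.12-fold. All 5 CD8 T cell genes were lower, with a median change of -2.08, and CCL5 (11.9-fold) and CD8A (3.09-fold) fell when adjusted over the list alone. Camera gave adjusted p of 0.019 for the lowered genes, 0.0078 for interferon-stimulated, 0.0084 for TGF-beta, 0.0011 for ribosomal and 0.040 for CD8 T cell genes. With an estimated correlation none of these 5 passed (adjusted p = 0.78, 0.78, 0.70, 0.77 and 0.78). The lowered genes did not pass without SS clonal 2 or 3 (adjusted p = 0.065 and 0.053), the interferon-stimulated genes without SS clonal 2 (median 0.12, adjusted p = 0.19) and the CD8 T cell genes without SS clonal 2 or 3 or healthy donor 1 (adjusted p = 0.15, 0.11 and 0.099). Without SS clonal 3 the interferon median was 0.998 and the TGF-beta median -0.27 (-0.45 with it), and without SS clonal 2 the ribosomal median was -0.12 (-0.19 with it), each with its list still past the test. Proliferation genes had a median of 0.25 and did not pass (adjusted p = 0.23). CD8A was above background on 1 of 3 SS clonal arrays, FAS and TGFB1 on 2 of 3, and RIGI on 2 of 3 healthy donor arrays. Erythroid genes were higher beside them, with HBB at 12.43 ± 1.91 against 8.13 ± 1.42 in healthy donors (list adjusted p = 0.087).

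Over all features 1244 passed between SS clonal patients and healthy donors, 580 higher and 664 lower, and 284 and 325 of these changed at least 2-fold. The values of the 2 groups did not overlap for 34.1% of the features, against 10% by chance. The count fell to 73 without healthy donor 1, 560 without healthy donor 2, 123 without healthy donor 3 and 488 without SS clonal 3, and was 1904 without SS non-clonal 1, which shares the estimate of the spread. It was 2292 with array weights and 525 with the level of NK and CD8 T cell markers as a covariate. With median scaling 774 were higher and 334 lower, and the median of all features shifted by 0.13.

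In SS non-clonal patients, with a lower burden, 2 features passed against healthy donors by limma, both lower, and 2570 had an unadjusted p below 0.05. SC5D fell 4.83-fold, from 12.08 ± 0.31 to 9.81 ± 0.24 (adjusted p = 0.048), and the long non-coding RNA PSMD6-AS2 fell 2.65-fold (adjusted p = 0.048). The next genes by unadjusted p failed the test: CHN1, a Rac GTPase-activating protein, at -1.71 (adjusted p = 0.071), ALOX5AP, which activates 5-lipoxygenase, at 1.12 (adjusted p = 0.090) and TCEAL2, above background on 2 of 3 SS non-clonal arrays, at -1.45 (adjusted p = 0.090). CD164 was 0.93 higher (adjusted p = 0.14), close in size to its change in SS clonal patients. The values did not overlap for 25.9% of the features, against 10% by chance. The calls of SC5D and PSMD6-AS2 were lost in 12 and 14 of 21 other settings. Leaving out 1 sample gave 0 to 4 features: 0 without SS clonal 2 or 3, SS non-clonal 1 or 2 or any healthy donor, 4 without SS clonal 1, and without SS non-clonal 3 there were 2, neither of them SC5D or PSMD6-AS2. The fits with 0 features had 1750 to 2739 at an unadjusted p of 0.05, and array weights gave 492 features.

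By camera, proliferation genes were higher in SS non-clonal patients for 27 of 27 members, with a median change of 0.78 (adjusted p = 2.55e-07, adjusted p = 0.79 with an estimated correlation), and MCM3, KIF11, PCNA and NUSAP1 rose by 1.92-fold to 2.79-fold when adjusted over the list alone. This rested largely on SS non-clonal 2, whose level was 9.09, against 7.25 and 7.70 in SS non-clonal 1 and 3 and 6.94 to 7.49 in healthy donors, and without it the median was 0.25 (adjusted p = 0.0038). Ribosomal protein genes had a median of -0.04 and did not pass (adjusted p = 0.37). Interferon-stimulated genes were higher for 22 of 25 (adjusted p = 0.00012, adjusted p = 0.79 with an estimated correlation), and OAS1, OAS2, OASL and IFI35 rose adjusted over the list alone. Naive and central memory genes were lower for 9 of 10 (adjusted p = 0.027, adjusted p = 0.57 with an estimated correlation), with LEF1 at -1.50 and CCR7 at -1.37, neither of which passed. NADH dehydrogenase subunits were higher for 21 of 27 (adjusted p = 0.029, adjusted p = 0.57 with an estimated correlation), with NDUFB3 at 0.79 and NDUFA8 at 0.60, neither of which passed. The naive and central memory list did not pass without SS non-clonal 3 (adjusted p = 0.056) and had a median of -0.41 without SS non-clonal 1 (-0.75 with it), nor did the NADH dehydrogenase list without SS non-clonal 1 or 2 (adjusted p = 0.054 and 0.067). NK cell genes were higher for 9 of 10 members, with a median change of 1.26 (adjusted p = 0.097), and PRF1, the pore-forming protein of cytotoxic granules, rose 7.10-fold when adjusted over the list alone.

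The contrast of SS clonal with SS non-clonal patients tested whether their changes against the shared healthy donors differed. Among genes whose single values did not overlap, PLS3 was 51.6-fold higher in SS clonal patients (adjusted p = 0.022), DNM3 22.6-fold (adjusted p = 0.015), CHN1 16.9-fold (adjusted p = 0.00018), the small GTPase RAB25 11.7-fold (adjusted p = 0.029) and CEMIP at least 8.50-fold (adjusted p = 0.021), as it was not above background on any SS non-clonal array. PLS3 and DNM3 were at 6.47 ± 0.15 and 6.41 ± 0.20 in SS non-clonal patients, near the healthy donors at 6.57 ± 0.16 and 6.67 ± 0.36. In SS non-clonal patients PLS3, DNM3 and RAB25 were above background on 1 of 3 arrays, so the size of these differences is uncertain. CHN1 was 11.83 ± 0.09 in SS clonal patients, 9.47 ± 0.11 in healthy donors and 7.75 ± 0.42 in SS non-clonal patients. SYTL2, which acts in granule transport, was 14.2-fold lower in SS clonal patients (adjusted p = 0.012), SMAD7 12.4-fold (adjusted p = 0.024), PRF1 11.9-fold (adjusted p = 0.044), AUTS2 10.7-fold (adjusted p = 0.034) and HOPX 10.3-fold (adjusted p = 0.025). Under other settings the calls of PRF1, AUTS2, HOPX and RAB25 were lost in 13 of 21, 10 of 20, 9 of 21 and 9 of 20, that of CHN1 in none and those of the other 5 genes in 3 to 6. With the marker covariate, to which PRF1 itself contributes, the log2 differences of PRF1, AUTS2 and SMAD7 were -2.41 (SE 0.66, from -3.58 with SE 0.66), -2.42 (SE 0.57, from -3.41 with SE 0.56) and -2.67 (SE 0.52, from -3.63 with SE 0.53). That of HOPX was -2.26 (SE 0.35, from -3.36 with SE 0.50), and -1.78 with the mean of its probes. The fitted log2 differences of PLS3, DNM3 and CEMIP were 5.36, 4.002 and 3.48 (from 5.69, 4.50 and 3.65). Those of RAB25, SYTL2 and CHN1 were 3.86, -3.83 and 4.42 (from 3.55, -3.82 and 4.08). For PLS3 the SE rose from 0.79 to 1.08 and for SYTL2 from 0.43 to 0.60. Of the 10 genes only CHN1 passed with the covariate, where 17 features were called. The largest unadjusted p called by limma was then 5.12e-05 instead of 0.00062, so a lost call alone does not show a smaller difference. CD164 differed by -0.04 between the patient groups (adjusted p = 0.96) and DPP4 by -1.68 (adjusted p = 0.11).

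Genes described as raised in Sézary cells were higher in SS clonal than in SS non-clonal patients for 20 of 23 members, and 7 rose (14 adjusted over the list alone), among them GTSF1 and the growth regulator MYC (3.97-fold, adjusted p = 0.029). This list passed with an adjusted p of 6.44e-11 by camera and an adjusted p of 0.0070 with an estimated correlation. Th1 genes were lower for 10 of 12 members, with a median of -1.32, and 5 fell when adjusted over the list alone, with IL18R1, IL18RAP, RUNX3 and EOMES 3.63-fold to 7.28-fold lower (IL18RAP was above background on 1 and EOMES on 2 of 3 SS clonal arrays). NK cell genes were lower for 10 of 10 members, with a median of -2.79, and only PRF1 passed over all genes. CD8 T cell genes were lower for 5 of 5 members, with a median of -3.13, and GZMA (8.78-fold), CD8A (4.16-fold) and CCL5 (13.2-fold) fell when adjusted over the list alone. Proliferation genes were lower for 25 of 27 members, with NUSAP1 at -1.13 (adjusted p = 0.18) and MCM6 next in size (adjusted p = 0.085), neither of which passed. Ribosomal protein genes were lower for 45 of 62, with RPL26 1.67-fold lower (adjusted p = 0.036). Immediate early genes were higher for 14 of 18, among which MYC rose. These 6 lists passed camera, with adjusted p of 0.00097, 0.00097, 0.0010, 0.0010, 0.0010 and 0.011 in that order, and none passed with an estimated correlation (adjusted p = 0.37, 0.49, 0.49, 0.60, 0.49 and 0.60).

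Single samples moved with these lists. The median of the NK cell genes was 12.44 in SS non-clonal 3, 10.31 in SS non-clonal 2 and 7.56 in SS non-clonal 1, against 6.56 to 8.10 in SS clonal patients and 7.36 to 9.08 in healthy donors. Without SS non-clonal 3 the median difference was -1.56 for NK cell genes (adjusted p = 0.020) and -0.64 for Th1 genes (adjusted p = 0.0016). The CD8 T cell genes were at 13.83 in SS non-clonal 3 and 8.80 in SS non-clonal 1. Immediate early genes were at 10.14 in SS non-clonal 1 and between 12.69 and 13.42 in the other 8 samples, and without SS non-clonal 1 that list's median difference was -0.03 (adjusted p = 0.94). Proliferation genes were at 9.09 in SS non-clonal 2, and without it that list's median difference was -0.02 (adjusted p = 0.71), while it was -0.81 without SS non-clonal 1. Without SS clonal 2 the ribosomal median difference was -0.10 (adjusted p = 0.030).

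In total 203 features passed between the patient groups, 110 higher and 93 lower in SS clonal patients, of which 89 and 63 differed at least 2-fold. The values of the 2 groups did not overlap for 19.2% of the features, against 10% by chance. The count was 38 without SS clonal 3, 330 without SS clonal 1, 19 without SS non-clonal 3, 122 without SS non-clonal 1, and 19, 67 and 54 without healthy donor 1, 2 and 3, which enter through the shared spread. It was 113 with no filter, 134 with features above background on all 9 arrays, 16 in a fit of the 2 patient groups alone and 17 with the NK and CD8 T cell marker covariate, and with median scaling 98 were higher and 52 lower.

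**Figure D3:**
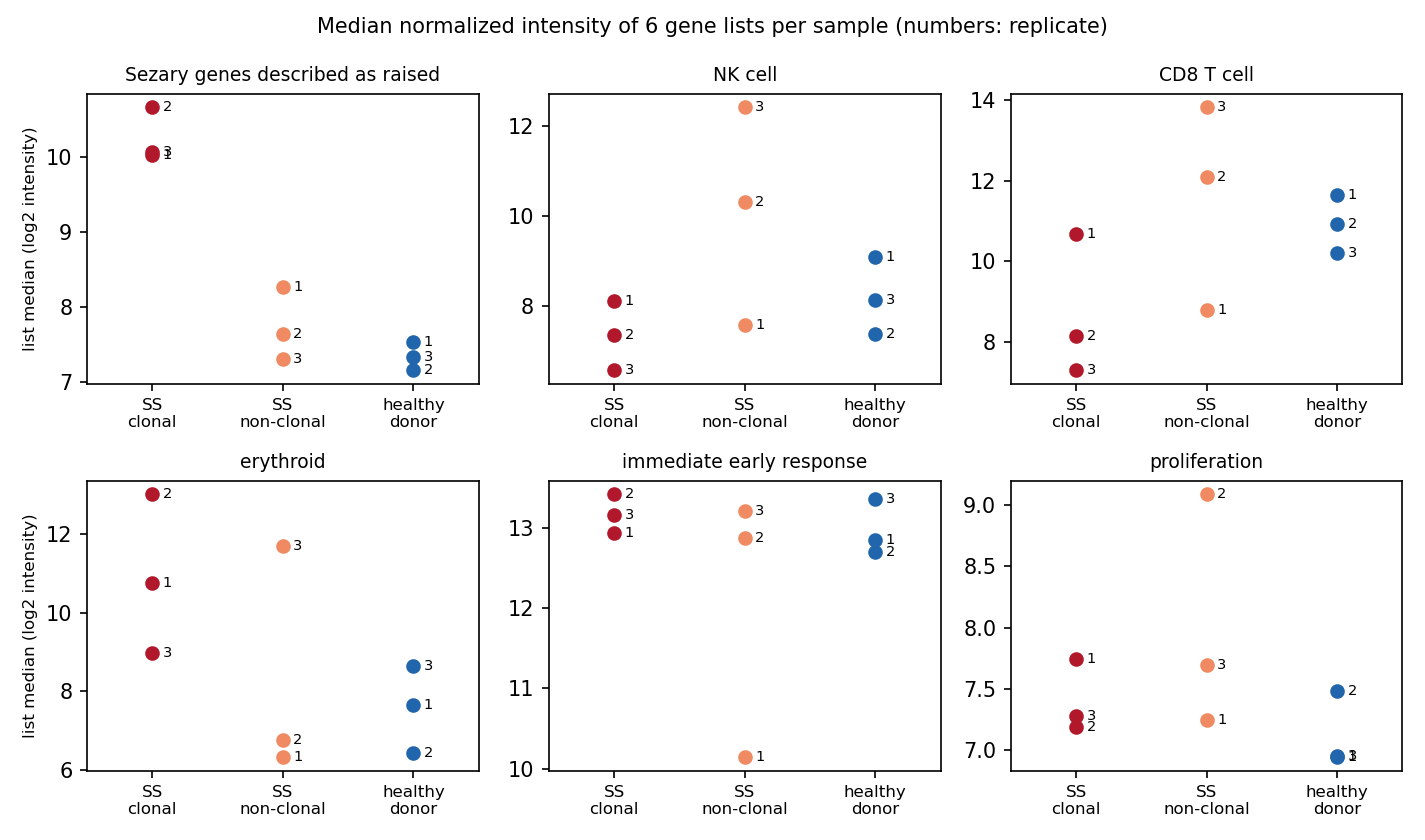
Median normalized intensity (log2, vertical axis) of 6 gene lists in each sample (points, numbered by replicate) of the 3 groups. NK cell and CD8 T cell genes were highest in SS non-clonal 3, at 12.44 and 13.83, and immediate early genes were at 10.14 in SS non-clonal 1.

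The changes of the patient groups against the shared healthy donors correlated across features with r = 0.52, where simulated unchanged groups against the same controls gave 0.50 ± 0.01 (SD over 100 simulations). Features are not independent replicates. The covariance was 0.124 against a simulated 0.038, a difference of 0.086. The sign was shared by 72.0% of the features against 66.6% in the simulation. Both comparisons called 2 features lower, against 0.081 for independent lists and 0 in every simulation, and none higher. The simulated groups held no change, so hardly any feature could be called in them, and the value for independent lists ignores the shared donors. Neither value can therefore show whether the 2 shared calls exceed what shared donors give. The simulation treats features as independent. Reshuffling whole arrays of residuals with no effect, a test chosen after the data were seen, gave r of 0.46 ± 0.31 (SD), from -0.64 to 1. Of 100 draws 44 were as high as the observed 0.52, so r shows no excess over these draws. Residuals of the 3 arrays of a group cancel when drawn together with like signs, so the spread of these draws is itself uncertain. Covariances were from -0.022 to 0.127, with 1 of 100 draws as high as the observed value. Parts of 2 donors each were not possible with 3 donors. With 1 donor behind 1 patient group and the other 2 behind the other, the 6 choices gave a mean r of 0.38 (0.24 to 0.46) and a mean covariance of 0.101 (0.068 to 0.117). Without effect the reshuffled arrays gave mean r from -0.80 to 0.46 and mean covariances from -0.096 to 0.073. As 1 of these parts holds a single donor, the values are imprecise, and some of the excess with shared donors may come from the shared controls.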

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

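The tests of spread, dilution and cell types were chosen after the results were seen, and those of splits and of matched lists on all samples before. Genes and lists are given here because the effects of SS clonal and SS non-clonal patients against the shared healthy donors differed in a test of the difference itself (limma, or camera for lists).

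Higher in SS clonal patients, on the log2 scale, were PLS3 by 5.69, DNM3 by 4.50, CHN1 by 4.08, CEMIP by 3.65, RAB25 by 3.55, GTSF1 by 2.80, TWIST1 by 2.68, MYC by 1.99 and IKZF2 by 1.43. The CEMIP value is a fitted difference against a group below background, and PLS3, DNM3 and RAB25 were above background on 1 of 3 SS non-clonal arrays. Lower were RPL26 at -0.74, NDUFB8 at -0.86, FAS at -1.13, TGFBR2 at -2.24, HOPX at -3.36, AUTS2 at -3.41, PRF1 at -3.58, SMAD7 at -3.63 and SYTL2 at -3.82, with FAS, AUTS2 and SMAD7 above background on 2 of 3 SS clonal arrays. The calls of PRF1, AUTS2, HOPX and RAB25 were lost in 13 of 21, 10 of 20, 9 of 21 and 9 of 20 other settings. Adjusted p of these 18 genes ranged from 0.000177 for CHN1 to 0.0443 for PRF1. The list medians differed by 1.497 for genes described as raised in Sézary cells, which also passed with an estimated correlation (adjusted p = 0.0070). The other 6 lists did not pass with an estimated correlation (adjusted p from 0.37 to 0.60). Their medians differed by 0.83 for immediate early genes, -1.32 for Th1, -0.48 for proliferation, -0.15 for ribosomal protein, -2.79 for NK cell and -3.13 for CD8 T cell genes. Without SS non-clonal 1 the immediate early difference was -0.03 (adjusted p = 0.94), and without SS non-clonal 2 the proliferation difference was -0.02 (adjusted p = 0.71).

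The first pattern is the 1244 features called in SS clonal against 2 in SS non-clonal patients, from a fit with 1 spread for all groups. In fits of 2 groups SS non-clonal patients, tested with the spread of SS clonal and healthy arrays, had 17 features (0 to 100 without single arrays). SS clonal patients had 1427 (22 without healthy donor 1 and 21 without healthy donor 3). Array weights, lowest at 0.391 for SS non-clonal 1, gave 492 features in SS non-clonal and 2292 in SS clonal patients. The fit with 1 spread for all groups gave each feature the same standard error in both comparisons. The spread of the non-clonal arrays alone could thus not lower only their count. The median SD of a feature was 0.232 in SS clonal, 0.221 in SS non-clonal and 0.164 in healthy donor arrays. These values argue against a larger spread among the non-clonal arrays as the cause, but single arrays moved both counts. Tumor cells diluted by normal T cells would place SS non-clonal patients between the others. The slope of their changes on those of SS clonal patients was taken over the 1244 features, with different healthy donors behind each. With 1 donor behind SS clonal and 2 behind SS non-clonal patients it was 0.336 (0.295 to 0.389). Simulations of this choice with no change in SS non-clonal patients and features called anew gave -0.142 to 0.226. The reverse choice gave slopes of 0.259 to 0.403 and was not simulated. The slope meets what dilution needs, but an effect of the disease shared by both groups could give it too. Of the 203 features called between the patient groups, 27.6% lay beyond healthy donors in SS non-clonal patients, away from SS clonal patients. The distance was over 2 standard errors. Simulated dilution gave 2.67% (0.962 to 4.53), but with noise independent between features. It leaves out shifts shared across whole arrays, so it cannot decide whether dilution is the whole cause for these. The burden and clonality that define the groups remain open as a biological explanation, and no batch could be tested.

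The second pattern is that cytotoxic genes were higher in SS non-clonal than in SS clonal patients, with medians of 15 genes at 10.70 ± 2.65 and 7.62 ± 1.07 against 9.23 ± 1.16 in healthy donors (SD, n = 3). With SS clonal values taken at or above background, CD8A differed by 1.71, and by at least 1.09 on leaving out 1 patient array. CD8A was at 7.48, 8.09 and 9.64 in SS non-clonal patients, 5.86 to 7.11 in SS clonal patients and 7.56 to 8.23 in healthy donors. Of the SS non-clonal patients only SS non-clonal 3 lay above the healthy donors, while all SS clonal patients lay below them. CD8 T cells in the preparations may contribute, but CD8A does not tell this from a loss in SS clonal preparations. The NK receptor genes KLRF1 and KLRD1, with TYROBP, a gene of the monocyte list, differed by a median of 1.41, but by 0.179 without SS non-clonal 3. KLRF1 alone differed by 2.51 (0.994 without SS non-clonal 3), KLRD1 by 1.41 (0.179) and TYROBP by 0.81 (-0.008). KLRF1 was above background on 1 of 3 SS clonal arrays and KLRD1 on none, which leaves NK cells undecided. A loss of non-malignant T cells in SS clonal preparations could lower the same genes. It would not raise SS non-clonal patients above healthy donors, where the median difference was 1.13, within the spread of 2.65, so this stays undecided.

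The third pattern is the higher proliferation and interferon-stimulated genes and lower ribosomal protein genes in the comparison of all patients with healthy donors, where patient arrays had more probes above background. Proliferation genes did not pass in SS clonal patients (median 0.25, adjusted p = 0.23) nor ribosomal protein genes in SS non-clonal patients (-0.04, adjusted p = 0.37), against 0.78 (0.25 without SS non-clonal 2) and -0.19 in the other group. A level-dependent shift between patient and healthy arrays could move whole lists. Among 10000 random lists matched on mean level, the medians lay at percentile 100 for proliferation, 100 for interferon-stimulated and 0.04 for ribosomal protein genes, and on leaving out single samples the first pair stayed at 99.84 or above and the last at 0.96 or below, which argues against such a shift as the whole cause. None of these lists passed with an estimated correlation, and a batch between patients and healthy donors could not be tested.

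In 1 of the 100 splits drawn of the 9 arrays, the real one, all patients against healthy donors gave 557 features or more. The highest of the other splits drawn gave 310. A share of 1% is the smallest that 100 draws can give, so this argues against a split by chance without excluding it. For 3 arrays against 3 the 10 splits are too few for a share under 0.05. As many features came in 1 of 10 splits, the real one, for SS clonal (1244, highest other 0) and SS non-clonal patients against healthy donors (2, highest other 1), and for SS clonal against SS non-clonal patients (203, highest other 10).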

How the results depend on the processing

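The level of NK and CD8 T cell markers as a covariate, the offset of 16, and median scaling and cyclic loess for gene lists were chosen after seeing the data. A slide block was not run, as the files give no slide, and the planned offset of 50 became the setting used. Few arrays, and for dim genes a signal near background, limit these results. Fits with fewer samples or groups have a less certain spread and those with no filter adjust over more features, and for the other settings the cause was not tested. No paired analysis was possible because replicate numbers follow sample order.

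Array weights gave 2572 features for all patients, 2292 for SS clonal and 492 for SS non-clonal patients against healthy donors. The 6 patients as 1 group gave 166. The marker covariate gave 525 for SS clonal and 9 for SS non-clonal patients, and 17 between the patient groups. SS non-clonal patients had 0 features with an offset of 16, median scaling, the mean of probes, every probe on its own or only the groups compared (2471 to 3268 at an unadjusted p of 0.05), and 1 with cyclic loess or the trend and robust model. Between the patient groups there were 113 with no filter, 134 above background on all 9 arrays and 16 with only the groups compared. Leaving out 1 sample gave 0 to 572 for all patients, 73 to 1904 for SS clonal and 0 to 4 for SS non-clonal patients, and 19 to 330 between the groups.

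With no filter CD164 was 0.91 over all patients (adjusted p = 0.054, limma). FCRL3 passed with array weights (2.40) and the covariate (2.34), and DPP4 with array weights (-1.05). Leave-one-out values ranged from 0.76 to 1.001 for CD164, 1.80 to 2.72 for FCRL3 and -1.32 to -0.90 for DPP4. CD164 between the patient groups turned to 0.0795 with array weights, 0.10 with the covariate, 0.12 without SS clonal 2 and 0.07 without SS non-clonal 3, and reached -0.21 without SS clonal 1.

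Of the gene lists 1 passed with an estimated correlation and 1 with fry, and 4 to 7 without single samples. The CD164 and DPP4 correlation turned to -0.14 without the 2 farthest samples and ranged from -0.18 to 0.44 without single samples. The correlation of the patient groups' changes ranged from 0.50 to 0.58 without single healthy donors. Of 47 results for named genes 47 kept direction and call with the authors' values, and 8, 21 and 13 without healthy donor 1, 2 and 3. These include the differences of CD164, FCRL3 and DPP4 between the patient groups, which were not called and count as kept when they stayed uncalled.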

Other observations

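Other T cell genes passed in SS clonal patients against healthy donors (limma, n = 3 each), from lists of T cell states and pathways that did not pass camera (adjusted p from 0.066 to 0.51). TIGIT, GATA3 and MYC also belong to the genes described as raised in Sézary cells, a list that passed. TIGIT, an inhibitory receptor, rose 4.41-fold (adjusted p = 0.032), GATA3, the Th2 transcription factor, rose 3.13-fold (adjusted p = 0.031), and IKZF2, which encodes Helios, rose 2.73-fold (adjusted p = 0.0091). MYC rose 4.31-fold (adjusted p = 0.012), LAT, an adaptor of T cell receptor signalling, 2.15-fold (adjusted p = 0.038) and TRAF1 1.93-fold (adjusted p = 0.028). In the Th1 list 3 of 12 genes fell, from 9.64 ± 0.88 to 6.86 ± 0.67 for IL18RAP (adjusted p = 0.024), from 9.78 ± 0.81 to 7.38 ± 0.99 for IL18R1 (adjusted p = 0.037) and from 9.77 ± 0.70 to 7.77 ± 0.62 for CXCR3 (adjusted p = 0.048), with IL18RAP above background on 1 of 3 SS clonal arrays. CD8 T cell genes were lower for 5 of 5 members (median -2.08) and NK cell genes for 8 of 10 (median -0.72, list adjusted p = 0.25). The CD8 list passed camera (adjusted p = 0.040) but not with an estimated correlation (adjusted p = 0.78), nor without SS clonal 2 or 3 or healthy donor 1 (adjusted p = 0.15, 0.11 and 0.099). A share of other cells in the Th1 falls was not tested. BACH2, a transcriptional repressor of the naive and central memory list, fell by 2.08 on the log2 scale (adjusted p = 0.035). Of 27 NADH dehydrogenase subunits 3 rose and 2 fell, with NDUFB3 at 1.02 and NDUFB7 at 0.53 against NDUFS5 at -0.85 and NDUFB8 at -0.75. The 9 arrays were weighted from 0.391 for SS non-clonal 1 to 3.98 for healthy donor 1 in the fit with array weights.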
